A study of Homo sapiens with 3 samples.

How the data were processed

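Binding of p63 was measured by CUT&Tag in TYUC-1 cells, a human esophageal neuroendocrine carcinoma line, in which ΔNp63, the shorter form of the transcription factor p63, was placed under doxycycline control. CUT&Tag directs a transposase to an antibody on chromatin, so that DNA near the bound protein is cut and tagged for sequencing. Per the labels, the cells of all 3 samples received doxycycline at 1 µg/ml for 16 h. The samples were 1 library with a non-specific antibody (IgG) and 2 technical replicates with an antibody against p63α. Samples without doxycycline were not among those used here, and no file of the IgG library was analysed here.

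The deposited files are 1 peak list per p63 replicate. Per the submitters' processing notes, the tools used were HISAT2, MACS2, deepTools 3.3.2 and ChIPseeker 1.28.3 on the build hg38; their roles and settings are not given in the sources used here. Each deposited list gives, per peak, the fold enrichment (a ratio over the local background) and −log10 values of p and q at the summit, as the authors' peak caller wrote them. The deposited score is the whole part of 10 times −log10 q. Each list has its own peak names and numbering, so peaks were called per replicate and not on pooled reads. Which library served as control, and whether duplicate reads were removed, is not given in the sources used here. The protocol in the labels names antibodies against histone marks, BRD4 and IgG, and not the p63 antibody.

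The number of extended reads over each summit was recovered from the fold enrichment and the −log10 p. The peak caller writes the fold as the pileup plus 1 over the background plus 1, and p as the upper Poisson tail of the pileup at that background. The rule fixed before the data were examined took the pileup as a whole number; it gave a whole number within 0.02 reads for 24.8% of the peaks of replicate 1 and 19.5% of those of replicate 2. A form with a scaling factor for each list was therefore chosen after seeing the data. It gave a unique whole number for 97.4% of the peaks of replicate 1 and 99.7% of those of replicate 2, with the same tolerance of 0.02 reads. The backgrounds so found equalled, within 0.01 reads, the genome mean, a whole number of control reads in 1 kb or 10 kb, or a whole number of control reads over the summit. On simulated peaks with these settings, 99.1% and 99.8% were resolved, with the true pileup in 100% of them.

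The scaling factors place the depth of replicate 1 at 3.60 times and of replicate 2 at 4.49 times that of the control. The background per base was equal in both lists to within 1.30e-05%, so both were called against a control of the same depth. With an assumed effective genome size of 2.7 Gb, which is not given in the sources used here, the control held 0.904 M reads, replicate 1 held 3.25 M and replicate 2 held 4.06 M. With a pileup median of 23 and 26 reads per peak, single control reads change the fold of a peak; precision is limited by this counting error.

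Peaks that overlapped by at least 1 bp were merged into regions, and a region was shared when it held a peak of each replicate. Chance overlap came from 100 random placements of the replicate 2 peaks on the same chromosomes. Genes were taken from an NCBI RefSeq table of assembly GRCh38.p14, the same assembly as hg38, which gives the span of each gene without strand or exons. The planned distance to transcription start sites was therefore replaced by the distance to either end of a gene, and exons, introns and untranslated regions were not assigned. No genome sequence was used, so the planned counts of p63 and other DNA motifs were not made. The correlation of fold that a shared control alone gives came from 100 shuffles of the replicate 2 pileups within 20 strata of background, a check chosen after seeing the data. On 8000 simulated regions with independent pileups, the simulated r differed from the mean of the shuffles by 0.0047. The random placements for the chance overlap and the random positions for all shares relative to genes avoided gene-free stretches of over 1 Mb.

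The territory of a protein-coding gene was the set of positions nearer to it than to any other protein-coding gene, up to 100 kb away. A position inside several genes went to the gene with the nearer end, so a gene that overlaps a region can count as not covered. The median territory was 54 kb. For 11 gene lists fixed before the data were examined, the members with a shared region in their territory were counted. That number was set among 10000 random lists of genes matched on territory length in 10 strata. All 290 list symbols were found in the table. A percentile describes these libraries and is no p-value, since genes are not replicates. In simulations over 19000 genes, 4.5% of lists drawn at random fell outside the central 95%. When 40% of the members without a region were given one, 86.5% of lists rose above it. All simulated lists had the same number of members, and their coverage was not set to that of these data. The 86.5% therefore need not hold for the lists used here, least of all for shorter ones. Smaller rises were not simulated, so a list inside the central 95% can still hold one.

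Named genes followed a rule fixed before the data were examined: the nearest gene of the 15 shared regions with the highest mean rank of fold, up to 4 members of each list with the best-ranked region, and 15 genes of interest. Genes named outside this rule are said to be so. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Alternatives were stricter peak thresholds, other definitions of sharing, each replicate left out, other gene assignments and, chosen after seeing the data, the recovered pileup in place of fold, regions without control reads, random lists also matched on the density of shared regions within 1 Mb of each gene, and the squamous list without keratins. Coordinates are 1-based. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.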

Results

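The series asks where p63, a master regulator of squamous epithelium, binds when ΔNp63 is induced in a neuroendocrine carcinoma line of the esophagus. The 2 technical replicates gave 11960 and 11658 peaks. The median peak of replicate 1 was 235 bp wide, with a fold enrichment of 5.54 (quartiles 4.67 and 6.94) and 23 extended reads over its summit. The median peak of replicate 2 was 254 bp wide, with a fold enrichment of 5.30 (quartiles 4.48 and 6.49) and 26 reads. The fold values are the authors' and describe peaks within their own list. Replicate 2 was 1.25 times as deep as replicate 1, as recovered from the lists. There was no biological replicate, so no value below carries an error between cultures, and no comparison with cells lacking induced p63 was made.

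The first question was which sites both replicates held. Shared regions numbered 9059, among them strong sites near RRM2, PXN, SORL1, SEMA3F and FGFR3. A further 2766 regions were found in replicate 1 alone and 2518 in replicate 2 alone. Of the peaks of replicate 1, 76.9% (95% interval 76.1 to 77.6) overlapped a peak of replicate 2, against a mean of 0.324% for randomly placed peaks. Shared regions had a median fold of 5.81 and 27 reads, whereas regions of replicate 1 alone had 4.78 and 18 reads and those of replicate 2 alone 4.35 and 18 reads. Across 8852 regions with 1 peak in each list, log2 fold correlated with a Pearson r of 0.722 and a Spearman rho of 0.687; these are correlations across peaks, which are not independent replicates. Both lists fit a control of the same depth, so their folds share a background. With reads shuffled among regions of like background, which keeps that sharing, r was 0.206 on average over 100 shuffles and at most 0.225, against 0.724 over the same 8621 regions. Over 2086 regions whose background was the genome mean in both lists, r was 0.757. Recovered reads over the summit, a measure chosen after seeing the data, correlated with r = 0.918 and rho = 0.913 across these 8621 regions. The shuffle was not run for reads. Shared regions with a control read over a summit had a median of 47 reads, against 23 without one. Such a read raises the background, and a higher background requires more reads for a peak to be called. How much of this r the shared background gives was therefore not measured. The variance of the split of reads between the replicates was 0.461 of that expected from binomial sampling. Over these regions the replicates differed by less than the sampling noise, but regions called in 1 list alone are left out, a selection that can lower the ratio. As technical replicates they were counted as 1 sample. Whether they share library molecules is not given in the sources used here, and shared molecules would raise both the overlap and the correlations. At a fold of 10 or more in both lists, the share of replicate 1 peaks that overlapped was 43.4% and 230 shared regions were left. Both lists were cut, so a replicate 2 partner with a fold under 10 counts as no overlap. The region in TP63, with a fold of 11.8 and 9.96, was lost in this way. The lower share is thus no measure of how well strong peaks were found again.

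**Figure D1:**
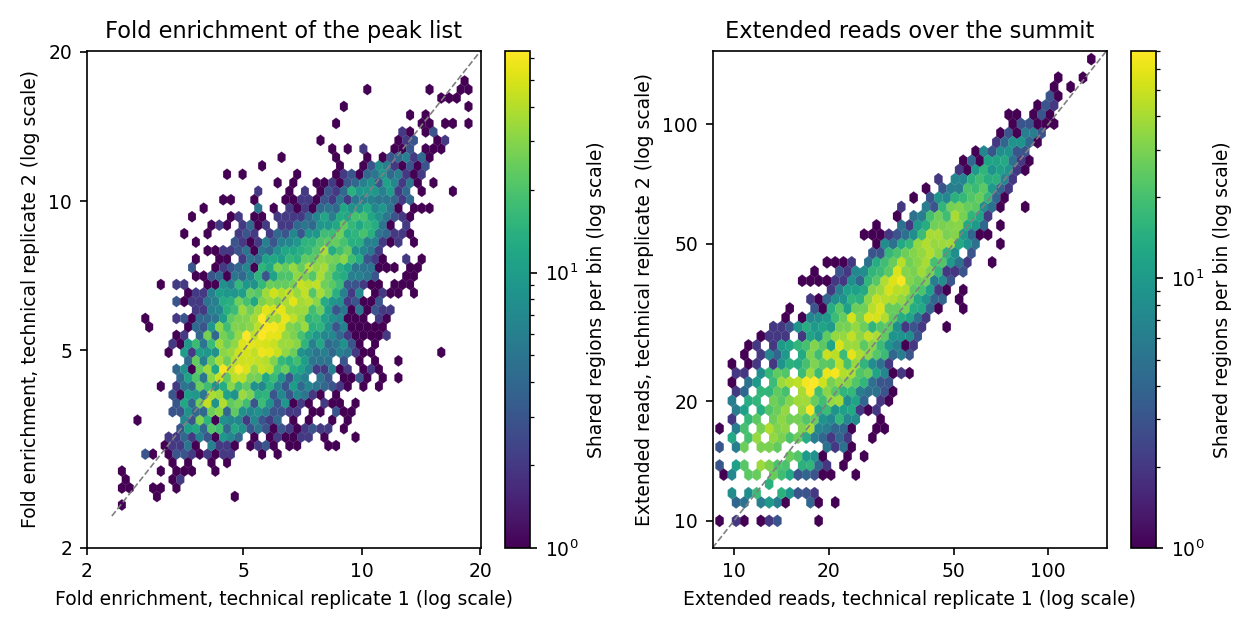
Each hexagon counts shared regions on chromosomes 1 to 22 and X by fold enrichment (left) and by extended reads over the summit (right), with replicate 1 on the x axis and replicate 2 on the y axis, all on log scales; the dashed line marks equal values. Pearson r on log2 values was 0.918 for reads (8621 regions) and 0.722 for fold (8852 regions). Both come from regions with 1 peak in each list, whereas the hexagons also count regions with several peaks. How much of the correlation of reads the shared control background gives was not measured.

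The strongest shared regions lay near genes of several kinds. The region ranked highest (GRCh38 chromosome 2, 10237250 to 10237846) lay 26.5 kb outside RRM2, a subunit of ribonucleotide reductase, with a fold of 18.6 in replicate 1 and 17.5 in replicate 2. The next lay 0.431 kb from PXN, which encodes the focal adhesion protein paxillin (chromosome 12, 120209809 to 120210335, fold 18.6 and 16.5). Regions inside SORL1, TSNARE1, GALNT9, DAB2IP, HDAC4, LTBP2 and ACTR3B were also among the 15 highest. The semaphorin genes SEMA3F, 1.03 kb from its region, and SEMA4F, 36.4 kb away, were both in this set, as was the growth factor receptor gene FGFR3 at 8.70 kb (fold 15.0 and 14.2). TPCN2 lay 30.5 kb from its region. LHX1 and LOC107985876 were the nearest protein-coding genes to the remaining 2, at 120 and 135 kb. Ranking by reads over the summit instead of fold left 0 of these 15 regions in the first 15, and the first 1000 regions of each ranking shared 274.

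The position of shared regions relative to genes was compared with random positions. Of 9051 shared regions on chromosomes 1 to 22 and X, 64.1% (63.1 to 65.1) lay inside a protein-coding gene, against a mean of 46.7% for random positions. Within 3 kb of an end of any annotated gene lay 29.5% (28.5 to 30.4), against 18.8%, and 18.5% lay within 3 kb of an end of a protein-coding gene, against 8.57%. Regions outside genes and over 100 kb from any protein-coding gene made up 5.08% (4.64 to 5.55), against 23.8%. Regions of replicate 1 alone were near gene ends in 37.3% (35.5 to 39.1) of cases and those of replicate 2 alone in 27.4% (25.7 to 29.2). Start and end of transcription were not told apart. Density was highest on chromosome 22, with 13.9 shared regions per Mb, and lowest on chromosome 18, with 1.13 per Mb.

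The design asks whether p63 regions lie at squamous genes in these neuroendocrine cells. Of 32 genes of squamous basal identity, 23 had a shared region in their territory, more than in any of the 10000 random lists, whose median was 7 and central 95% ran from 3 to 11. The folds given for a gene are those of its region with the best mean rank over both lists. Such a region can lie up to 100 kb outside the gene. KRT5, a keratin of basal squamous cells, had 2 regions, the stronger 1.11 kb from the gene (chromosome 12, 52521309 to 52521784) with a fold of 12.7 and 10.6. KRT14, its basal partner keratin, had 2 regions, the best-ranked with a fold of 6.26 and 5.61. KRT17 had 4, the best-ranked with a fold of 9.85 and 10.3, and the cadherin gene FAT2 had 2, the best-ranked with a fold of 9.39 and 8.17. SOX2, a squamous transcription factor gene, had no shared region in its territory, and the nearest lay 1242 kb away. TRIM29, named after its values were seen, had 8 regions.

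TP63 itself held 1 peak in each list within the gene and 20 kb on either side. It lay at chromosome 3, 189834018 to 189834247, in replicate 1 (fold 11.8, 45 reads) and 189834012 to 189834249 in replicate 2 (fold 9.96, 47 reads). The region was inside the gene, 63.1 kb from its nearer end. Whether it overlaps an exon was not assigned. Reads from a construct with a copy of the ΔNp63 coding sequence would align to TP63 exons. An origin of this peak in the construct was therefore not tested.

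Neuroendocrine genes did not stand apart from random lists. Of 38 neuroendocrine and neuronal genes, 6 had a shared region in their territory, against a random median of 10 and a central 95% of 5 to 15. No shared region lay in the territories of ASCL1, NEUROD1 and INSM1, transcription factor genes of the neuroendocrine lineage, or of SYP, CHGA and NCAM1, which encode common neuroendocrine markers. The nearest region was 714 kb from ASCL1, 3474 kb from NEUROD1 and 75.8 kb from INSM1. It was 3.09 kb from SYP, 17.6 kb from CHGA and 37.3 kb from NCAM1, assigned in each case to another gene. The members with the best-ranked regions were MYT1 with 5 regions (best-ranked fold 9.64 and 9.38), RET with 4 (mean fold 9.16), REST, a repressor of neuronal genes, with 2 (7.17 and 9.48), and ENO2 with 1 (7.20 and 7.64). The best-ranked region lay 36.2 kb outside RET and 10.1 kb outside REST, and inside the gene for MYT1 and ENO2. The percent of members covered was 56.1 points higher for the squamous than for the neuroendocrine list, above each of the 10000 pairs of random lists (central 95% from −23.8 to 15.5 points). Over other settings the gap ran from 43.1 points, with gene bodies and 10 kb either side, to 58.7 points, with summits within 100 bp, except in 4 smaller sets of regions. In these it was 28.0 points for distal regions only (1 random pair reached it), 18.6 points with −log10 q of 5 or more in both lists (34 random pairs), 13.5 points in the top 1000 regions by fold (6 pairs) and 18.8 points in the top 1000 by reads (1 pair). At that −log10 q, 11 squamous genes were covered against a random median of 3 and 6 neuroendocrine genes against 5.

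**Figure D2:**
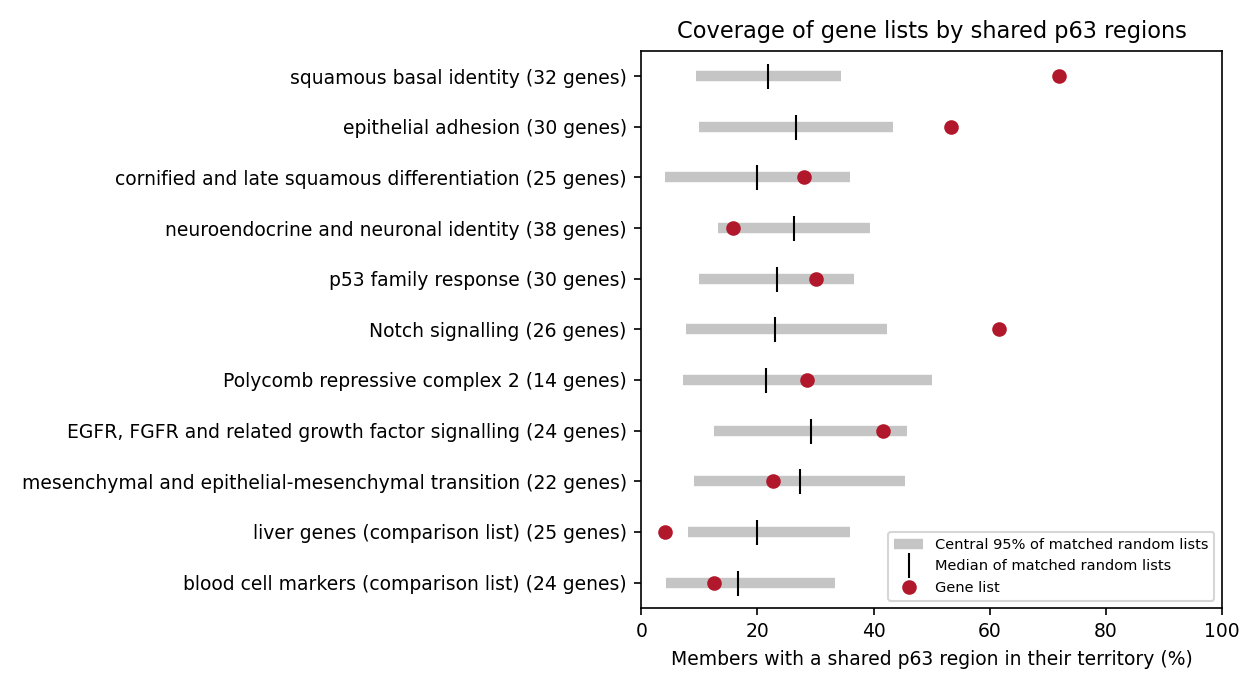
Red points give the percent of each list's genes with a shared p63 region in their territory, black ticks the median and grey bars the central 95% of 10000 matched random lists. The squamous basal (71.9%), Notch (61.5%) and epithelial adhesion (53.3%) lists lie above their bars and the liver list (4%) lies below.

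Adhesion and Notch genes were covered more than random lists as well. Of 30 epithelial adhesion genes, 16 had a shared region in their territory. The random median was 8 (3 to 13), and 17 of 10000 random lists reached 16. NECTIN1, an adherens junction gene, had 13 regions, the best-ranked with a fold of 16.2 and 13.0 (chromosome 11, 119671548 to 119672260). PLEC and PKP1, hemidesmosome and desmosome genes, had 5 each, with a mean best-ranked fold of 11.8 and 10.9; the integrin gene ITGA3 had 2 (11.3 and 9.64). Of 26 Notch pathway genes, 16 were covered, against a random median of 6 (2 to 11), which 1 of 10000 random lists reached. NOTCH1 had 6 regions, the best-ranked 37.2 kb outside the gene (fold 10.4 and 9.18). DLL1 had 5, all outside the gene, the nearest 54.4 kb and the best-ranked 99.8 kb away (10.9 and 10.7). MAML3 (9.65 and 10.3) and LFNG (9.53 and 8.10) had 4 each, the best-ranked inside MAML3 and 3.42 kb outside LFNG. JAG1 had no region in its territory. With genes assigned by body and 10 kb either side, 12 adhesion genes were covered against a random median of 8, within the central 95%. With −log10 q of 5 or more in both lists, 6 Notch genes were covered against 3, also within it.

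**Figure D3:**
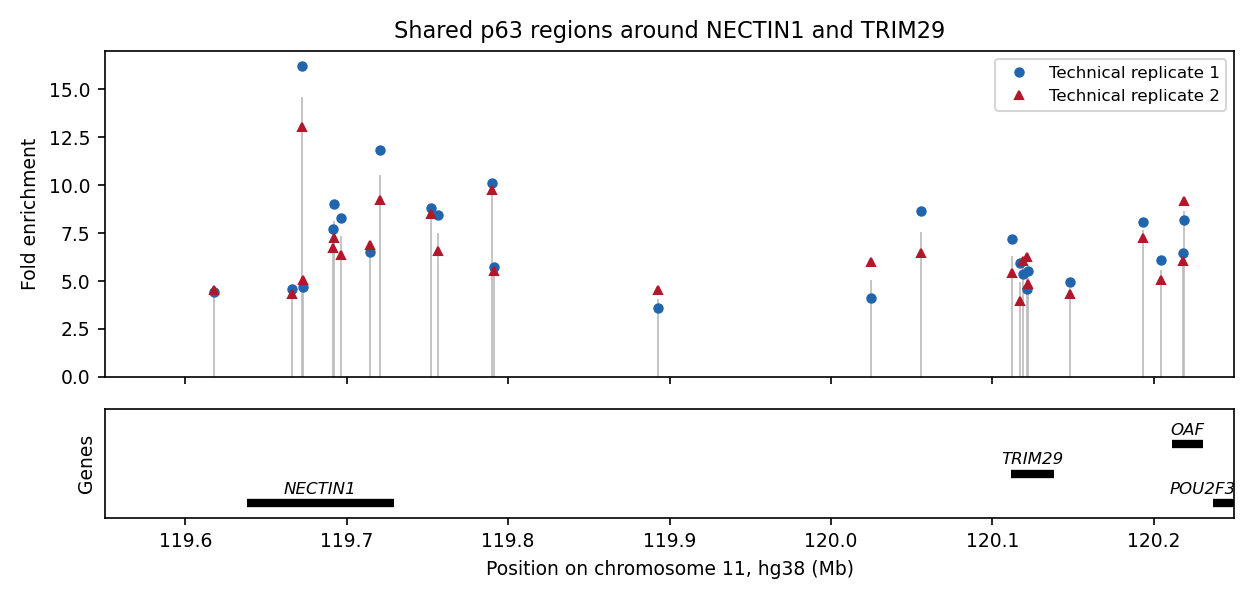
Shared p63 regions on chromosome 11 from 119.55 to 120.25 Mb (hg38, x axis) with their fold enrichment (y axis) in replicate 1 (blue circles) and replicate 2 (red triangles); grey lines reach the mean of both and black bars below are protein-coding genes. The window, chosen after seeing the data, holds 26 shared regions, the highest inside NECTIN1.

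The other lists lay within the central 95% of random lists, except the liver list. Of 25 genes of cornified and late squamous differentiation, 7 were covered against a random median of 5, among them CALML3 with 5 regions, CALML5 with 3, and PPL and RHCG with 1 each. Of 30 p53 response genes, 9 were covered against 7; CDKN1A, the cell cycle inhibitor p21, had 3 regions (best-ranked 4.11 and 6.96), GDF15 had 2, and BBC3, SESN2, TP53I3 and MDM2 had 1 each. With all peaks of replicate 1, 13 p53 response genes were covered against 8 (3 to 13), which 356 of 10000 random lists reached. With gene bodies and 10 kb either side, 12 were covered against 7 (3 to 12), which 359 reached. Both counts lie at the upper bound of the central 95%. Of 24 growth factor signalling genes, 10 were covered against 7; FGFR3 had 7 regions, IGF1R had 4, and MET and TGFA had 1 each. Of 14 genes of Polycomb repressive complex 2 and related factors, 4 were covered against 3, namely JARID2 with 6 regions, EZH2 with 2, and AEBP2 and KDM6A with 1 each. The best-ranked JARID2 region lay 97.4 kb outside the gene. Of 22 mesenchymal genes, 5 were covered against 6; SPARC had 2 regions, and TGFB1, SNAI2 and TGFBI had 1 each. Of the comparison lists, 3 of 24 blood cell genes were covered against 4 (CD14, SPI1 and ITGAM), and 1 of 25 liver genes, TF, against 5 (2 to 9). The liver list moved inside the central 95% with random lists also matched on regional density, where the random median was 3.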

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

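Of the shared regions, 8 lay on unplaced or unlocalised sequences of the assembly, which the comparisons with genes leave out. They are listed because both replicates held peaks there in data not otherwise used. Like the other peaks, they were called over the local control background. No explanation was tested for them.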

How the results depend on the processing

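Alternatives with the recovered pileup, control reads, regional density and keratins were chosen after seeing the data. Of 155 alternative values, 132 counted as unchanged. For this, shares stayed within their 95% interval, numbers of shared regions within 1.5 times and r within 0.05. Gene lists stayed inside, above or below the central 95% of random lists, as before. No gene list went from above the central 95% to below it or the reverse. The cause of the changes below was not tested.

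The share of replicate 1 peaks overlapping replicate 2 moved to 71.0% with 50% reciprocal overlap, 68.2% with summits within 100 bp, 60.4% with −log10 q of at least 5 and 43.4% with fold of at least 10. In the last 2 settings both lists were cut, so a partner under the cut counts as no overlap. Shared regions then numbered 3390 and 230. The r between replicates moved to 0.918 with pileups, where the part that the shared background gives was not measured. The gene-end share moved to 28.1% with −log10 q of at least 5, 30.9% in the top 1000 regions by fold, 33.3% in the top 1000 by pileup, 28.2% without control reads over a summit, 13.6% at 1 kb and 18.5% for protein-coding genes; over random positions, the ratio rose from 1.56 to 1.80 and 2.17 in the last 2. With each replicate left out it ran from 29.1 to 31.2%.

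As percentiles among random lists, adhesion fell to 91.7 with gene bodies and 10 kb either side, and Notch to 93.9 with −log10 q of at least 5. The p53 list rose to 97.53 with gene bodies, and ran from 95.1 to 97.52 with each replicate left out; its 2 highest values pass the bound by mid-rank only, at counts equal to it. It fell from 83.9, within the central 95%, to 12.9 for distal regions and 14.8 in the top 1000 by fold. In that top 1000, 0 p53 genes were covered against a random median of 1, and the central 95% began at 0. The neuroendocrine list rose from 7.7 to 69.8 with −log10 q of at least 5 and to 58.2 in the top 1000 by fold. In these moves the p53 and neuroendocrine lists crossed the middle of their random lists. They stayed within the central 95%, so they are counted as unchanged. The liver list moved to 2.88 with −log10 q of at least 5, 19.1 and 19.7 in the top 1000 by fold and by pileup, 4.05 for distal regions and 7.21 with density-matched lists. At that −log10 q and in both top 1000 sets, 0 liver genes were covered and the central 95% began at 0. A list cannot lie below the central 95% there, so these moves are no sign of higher coverage. The same holds for the neuroendocrine list in the top 1000 by pileup, with 0 genes covered. The motif alternatives were not run, for lack of a genome sequence. No paired analysis was possible because only 1 group has peak lists. Depth limits weak sites: peaks held as few as 9 reads.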

Other observations

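Gene families, chosen after seeing the data, differed in coverage by shared regions. Of 29 semaphorin and plexin genes, which guide axons and cell movement, 16 had a shared region in their territory, against a median of 7 in random lists (8 when also matched on regional density). Ephrins and Eph receptors had 11 of 23 covered, against 6 under either matching, and WNT and frizzled genes 13 of 29, against 7 (8 with density). Solute carriers had 123 of 386, against 91 (95 with density). Zinc finger genes had 58 of 517, against 116 (103 with density). Olfactory receptors had 3 of 392, against 72, but 36 with density, and protocadherins 0 of 65, against 9, but 4 with density. Keratins had 18 of 55 covered, against 10, but 17 when random lists were also matched on regional density. That density counts shared regions within 1 Mb of a gene and outside its own territory. Where family members lie near each other, it includes regions at the other members. For such families the match cannot separate regional density from the family's own coverage. Keratin-associated genes had 4 of 94, against 11 under either matching. In all, 23 families were counted, and those not named here lay within the central 95% of random lists matched on territory length. Integrin, HOX and forkhead genes were among these.

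Of the tests below, those of an even scatter of control reads, of gene ends, of dense stretches and of control-read sites for the squamous list, and of MAD1L1 were chosen only after the result was seen.

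Control reads lay over the summits of p63 regions. In replicate 1, 18.7% of peaks with a recovered pileup took their background from control reads over the summit. Peaks with such a read but a larger 1 kb or 10 kb background are not counted, so this share is a lower bound. An even scatter over the genome gives 4.64%, a ratio of 4.03, which argues against an even scatter. Regions with a control read so counted lay near a gene end 1.19 times as often as regions without (33.7% against 28.2%). That is too little for open chromatin at gene ends to be the whole cause. Regions with a control read had a median of 23 other shared regions within 1 Mb, against 17 without, a ratio of 1.35, which leaves a role of extra copies or denser signal open, because the ratio lies between the bounds set in advance. Among the top 1000 regions, 10.4% had a control read when ranked by fold and 78.5% when ranked by reads. No biological explanation was tested.

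The squamous list was covered more than random lists. It stood at percentile 100 of random lists also matched on regional density (23 covered against a median of 8), at 100 without the keratins (18 against 5) and at 100 without regions that have a control read over a summit (20 against 6). These values argue against dense stretches and neighbouring keratins as the whole cause. For control-read sites the last value speaks only of control reads counted over a summit. It also speaks only at the depth of this control, about 0.904 M reads at the assumed genome size. Of shared regions with both pileups recovered, 22.9% had a counted control read over a summit. Regions whose background came from control reads within 1 kb or 10 kb were kept. The best-ranked KRT5 region, with a 1 kb background of 0.568 reads in replicate 1 and 0.608 in replicate 2, is among those kept. Sites that the control shows in this way, and sites that only a deeper control would show, are therefore not excluded. Binding of p63 at squamous genes may account for the pattern, as a hypothesis; without cells lacking induced p63, binding that needs the induction is not separated from other signal.

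MAD1L1, named after its values were seen, had 42 shared regions in a territory of 452 kb. The median control background of these regions was 0.530 reads, against 0.147 for all shared regions. It stood at percentile 97.2 of 8025 runs of as many consecutive shared regions, which overlap each other. Among the 491 runs within 4 times its span of 399 kb, 73.5% had a lower median, and the median over these runs was 0.294 reads. Most dense stretches thus had a lower background than MAD1L1, but a background as high was not particular to it. Whether more copies or more background signal of this stretch account for its regions cannot be told apart from what dense stretches share. Open chromatin was not tested for this gene, and no biological explanation was tested.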
